A study of Homo sapiens with 6 samples.

How the data were processed

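Total RNA was extracted with TRIzol from SH-SY5Y cells 72 h after transfection with OE-NC or OE-circSHPRH, and sequencing libraries were made with a SMARTER mRNA-Seq kit, per the labels. The labels give 3 samples per group (replicates 1 to 3) and do not say that they came from separate cultures, so the p-values then measure only the spread between these samples, which may be technical. The deposited data are 1 table of 28752 genes. It holds raw read counts per gene and library, deposited by the authors without normalization. A second set of columns is a normalized count signal, which the authors made by dividing each library's counts by one size factor; this was worked out from the constant ratio of the deposited columns. The authors' deposited FPKM values are proportional to the count divided by the gene length within each library. The table also carries the authors' group means, log2 fold change, p-value and adjusted p-value per gene. The aligner, the counting tool, the use of strand and the authors' test are not given in the sources used here. The build named in the submitters' processing notes is GRCh37. The deposited coordinates, however, were identical to those of GENCODE release 29 on GRCh38 for 28727 of 28752 gene identifiers (99.9%), and coordinates are given as deposited, on GRCh38. DESeq2 run here on the deposited counts came within 6.36e-06 of every deposited p-value and within 2.51e-05 of every deposited log2 fold change. The deposited adjusted p is 1 for 21740 genes, and that of the top gene implies an adjustment over 7012 tests.

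Everything else was computed from the raw counts. The total per library ran from 15645261 to 17591718, so that 1 count equals 0.0568 to 0.0639 CPM. Genes were filtered with filterByExpr of edgeR 4.0.16 by group (minimum count 10, minimum total count 15), which left 16458 genes with 99.8% of the counts and left out 12294. Libraries were scaled with TMM factors and tested with edgeR's quasi-likelihood F-test (glmQLFit, glmQLFTest), two-sided, with group as the only term and Benjamini-Hochberg adjustment at 0.05. The common dispersion was 0.00287, a biological coefficient of variation of 5.36%. The standard error of a log2 fold change was taken as its absolute value over the square root of F. Mean and SD are of TMM-scaled CPM over 3 libraries. Fold changes are OE-circSHPRH over OE-NC, and a positive value is higher in OE-circSHPRH. OE-NC was taken as the negative control, since the labels do not spell out OE or NC. At an unadjusted p under 0.05, 1703 genes passed, where 823 would by chance. In 15.6% of the genes tested no library of one group overlapped the other group, against 10% by chance, and all 31 called genes were among them.

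Gene lists were written before the data were examined (33 lists, 598 genes, of which 556 were in the table used here, and the rest were not analysed here). The 30 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over these lists. With it 10 lists passed, 5 in each direction. Camera with an estimated correlation and fry were run beside it, and 1 and 8 lists passed. A call lost with the estimated correlation need not mean that members were correlated. The mesenchymal and heat shock lists had estimates of -0.014 and -0.020, below the preset. Their camera adjusted p still rose from 0.00428 to 0.124 and from 0.0462 to 0.271. These settings thus differed in more than the correlation. Members were also adjusted over each list alone. Some genes are members of several lists, such as CDKN1A.

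The genes named in the text follow a rule fixed before the data were examined. It takes SHPRH, CDKN1A, CDK1, CDK2, CDK4 and CDK6. It adds members of the CDK, cyclin and CDK inhibitor lists that passed. It adds up to 10 protein-coding genes per direction with the largest log2 fold change among those with an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap of replicates. It adds up to 4 members per list with the smallest adjusted p and, for lists that did not pass, up to 2 with the highest expression. Only 7 protein-coding genes fell, so fewer were named in that direction. Other genes are said to have been chosen after their values were seen, where they are named.

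The same code was tested on simulated counts for the 16458 genes, 5 times, with the same 200 genes changed each time. A list of 30 further genes was shifted by 0.15 on the log2 scale each time, and calls among them were not counted as false. edgeR called 49.3% of genes changed 1.25-fold, 81.5% of those changed 1.5-fold and 93.9% of those changed 2-fold. Of its calls 8.88% were false, above the 5% aimed at, against 5.05% with DESeq2 and 7.97% with limma-voom. In the last of these simulations the shifted list was called by camera and 0 of 30 unchanged lists were. The simulated genes varied independently, while the inter-gene correlations estimated in the data ran from -0.23 to 0.60 by list. The unchanged lists therefore say nothing about false list calls among correlated genes.

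Replicates of a group were compared gene by gene with a chi-square statistic over genes with a summed count of at least 20. It was 2.20 to 7.90 per degree of freedom, above sampling noise for every pair, so no library was counted as a copy of another. Alternatives fixed before the data were examined were DESeq2 1.42.0, its size factors or upper-quartile factors in edgeR, no low-count filter, a mean CPM of at least 1, limma-voom, the replicate number as a block, leaving out each library, an estimated correlation, and fry. Those for a table without counts were not needed. Added after seeing the data were a robust empirical Bayes fit, mitochondrial genes left out, removal of the GC and length trend, the percent of mitochondrial counts as a covariate, the p53 list without CDKN1A, and the library class (under or over 11% mitochondrial counts) as a term. R 4.3.3, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.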

Results

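SH-SY5Y is a human neuroblastoma cell line, grown from a tumour of the sympathetic nervous system. RNA sequencing was run on SH-SY5Y cells 72 h after transfection with OE-circSHPRH or with OE-NC, with 3 libraries per group. The labels do not spell out OE or NC, and OE-NC is taken here as the negative control. circ-SHPRH is a circular RNA of the SHPRH gene, and the series title ties the peptide it encodes to p21, the product of CDKN1A, and to the cyclin-dependent kinases (CDKs). Gene counts per library summed to 15657848, 17454486 and 17591718 in OE-NC and to 17244665, 15645261 and 16618288 in OE-circSHPRH, a ratio of 1.12 between the deepest and the shallowest library. Between 23926 and 24511 genes had at least 1 count in a library. Mitochondrially encoded genes took 10.6% ± 0.708 (SD, n = 3) of the counts in OE-NC and 11.2% ± 0.936 (SD, n = 3) in OE-circSHPRH. That share fell into separate ranges that cut across the groups. It was 10.2% to 10.3% in OE-NC replicates 1 and 2 and OE-circSHPRH replicate 3 (the low-share libraries), and 11.4% to 12.1% in OE-NC replicate 3 and OE-circSHPRH replicates 1 and 2 (the high-share libraries).

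The comparison asked which transcripts differed between OE-circSHPRH and OE-NC cells, with CDKN1A and the CDKs as the genes named by the title. SHPRH itself, which encodes a ubiquitin ligase acting on the replication clamp PCNA, was 2.91-fold higher in OE-circSHPRH. CDKN1A, which encodes the CDK inhibitor p21, was 1.34-fold higher. The list of targets of the transcription factor p53, CDKN1A among them, shifted upward and the lists of DNA replication and mitosis genes downward (camera adjusted p of 1.9e-11, 1.69e-14 and 1.79e-13). With an estimated correlation only the replication list passed (adjusted p = 0.0216), and the p53 and mitosis lists did not (adjusted p = 0.124 for both). Lists with an estimate below the preset correlation lost their calls too, so the loss is not by itself a sign of correlated members. Most of these shifts were small: the median absolute log2 fold change of the called genes was 0.35. Of 16458 genes tested, 21 rose and 10 fell at an adjusted p under 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). SHPRH was the only one of these 31 to change by 2-fold or more; none fell that far.

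SHPRH (ENSG00000146414, chromosome 6, 145864245 to 145964423, minus strand, GRCh38) rose from 25.1 ± 1.83 CPM (SD, n = 3) in OE-NC to 72.9 ± 8.90 CPM (SD, n = 3) in OE-circSHPRH. Its log2 fold change was 1.54 with a standard error of 0.083 (edgeR adjusted p = 2.26e-09). The raw counts behind these values were 394 to 472 per OE-NC library and 1071 to 1395 per OE-circSHPRH library. These are counts over the whole host gene, and the table does not separate the circular RNA, the linear mRNA or transcripts of the construct. CDKN1A (ENSG00000124762, chromosome 6, 36676460 to 36687339, plus strand) rose from 768 ± 3.08 CPM (SD, n = 3) to 1032 ± 39.0 CPM (SD, n = 3). Its log2 fold change was 0.43 with a standard error of 0.040 (edgeR adjusted p = 1.44e-05). No OE-circSHPRH library overlapped an OE-NC library for either gene. Within the low-share libraries the difference of mean log2 CPM was 1.41 for SHPRH and 0.48 for CDKN1A, and within the high-share libraries it was 1.51 and 0.40. Here and below, each such difference has a single library on one side and recuts the same libraries.

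**Figure D1:**
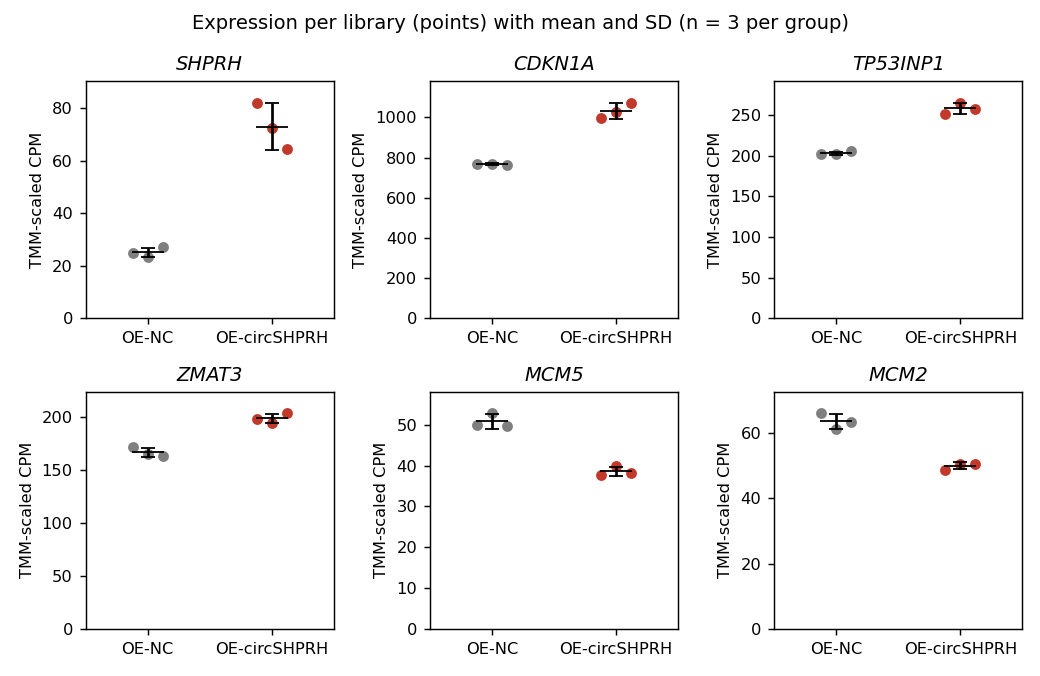
TMM-scaled CPM per library (y axis, from 0) of 6 genes in the OE-NC and OE-circSHPRH groups (x axis), with points for single libraries and bars for mean and SD (n = 3). All OE-circSHPRH libraries lie above all OE-NC libraries for SHPRH, CDKN1A, TP53INP1 and ZMAT3, and below them for MCM5 and MCM2.

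No CDK mRNA passed the test. Of the 5 CDKs of the cell cycle tested, CDK4 had a log2 fold change of -0.10 (SE 0.043, adjusted p = 0.396), CDK1 of -0.11 (SE 0.066, adjusted p = 0.608), CDK6 of 0.07 (SE 0.042, adjusted p = 0.576) and CDK2 of 0.05 (SE 0.067, adjusted p = 0.857), all by edgeR. The list had a median log2 fold change of 0.05 but a mean of -0.005, so that its median differed in sign from its mean and from camera (adjusted p = 0.957). None of the 9 cyclins tested passed either, over all genes or adjusted over the list alone, and the list's camera adjusted p was 0.192 with a median of -0.08. CCND1, the D-type cyclin that activates CDK4 and CDK6, had a log2 fold change of 0.11 (SE 0.040), and CCNE2, an E-type cyclin that activates CDK2, of -0.44 (SE 0.20). Of the 7 CDK inhibitors tested, CDKN1A alone rose, over all genes and adjusted over the list alone. CDKN1B, which encodes p27, had a log2 fold change of 0.07 (SE 0.043, edgeR adjusted p = 0.612). The inhibitor list as a whole did not pass (camera adjusted p = 0.316).

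Genes transcribed under p53 shifted upward as a group. Of 30 listed and tested, 27 had a positive log2 fold change, 4 rose over all genes and 16 rose when adjusted over the list alone. The median log2 fold change was 0.17, or 1.12-fold (camera adjusted p = 1.9e-11), against an adjusted p = 0.124 with an estimated correlation. After CDKN1A the genes that rose were TP53INP1, SESN1 and ZMAT3. TP53INP1 (chromosome 8, 94925972 to 94949411), a stress-induced p53 cofactor, rose from 203 ± 1.92 to 258 ± 6.90 CPM (SD, n = 3 each; log2 fold change 0.35, edgeR adjusted p = 0.000321). SESN1 (chromosome 6, 108986437 to 109094819), a sestrin that restrains mTORC1 signalling, had a log2 fold change of 0.29 (SE 0.054, adjusted p = 0.0315). ZMAT3 (chromosome 3, 179017223 to 179072279), an RNA-binding protein, had one of 0.25 (SE 0.043, adjusted p = 0.0151). The damage-recognition gene DDB2 (0.26), the kinase gene PLK2 (0.26) and the mitochondrial reductase gene FDXR (0.29), chosen after their values were seen, passed over the list alone but not over all genes. The list median was 0.20 within the low-share libraries and 0.16 within the high-share libraries. In the listed apoptosis effectors, several of which are p53 targets, no gene passed, over all genes or over that list alone, and the median log2 fold change was 0.0017 (camera adjusted p = 0.956). BAX, a member of both lists, had a log2 fold change of 0.12 (SE 0.047) and was among the 16 genes that rose over the p53 list alone (edgeR adjusted p = 0.0426). The inhibitors of apoptosis had a median of -0.0041 (camera adjusted p = 0.701), and none of their 8 tested members passed.

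Genes of the G1/S transition and DNA replication shifted downward. Of 35 tested, 34 had a negative log2 fold change, 2 fell over all genes and 18 fell when adjusted over the list alone. The median was -0.19, or 0.878-fold (camera adjusted p = 1.69e-14). This list alone kept its call with an estimated correlation (adjusted p = 0.0216). MCM5 (chromosome 22, 35400063 to 35425430) and MCM2 (chromosome 3, 127598223 to 127622436), subunits of the replicative helicase, were the members that fell. MCM5 went from 50.8 ± 1.74 to 38.6 ± 1.15 CPM and MCM2 from 63.6 ± 2.40 to 50.0 ± 1.03 CPM (SD, n = 3 each), with log2 fold changes of -0.40 and -0.35 (edgeR adjusted p = 0.00625 and 0.0140). E2F1, a transcription factor of S-phase genes, had a log2 fold change of -0.38 (SE 0.080, edgeR adjusted p = 0.057), and MCM4 had -0.25 (SE 0.055, adjusted p = 0.0788). Both passed over the list alone. The list median was -0.16 within the low-share and -0.18 within the high-share libraries. The same list was also lower in the high-share than in the low-share libraries (camera adjusted p = 0.048). That test used the preset correlation without a group term, and 2 of the 3 high-share libraries were OE-circSHPRH, so the group difference enters it.

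Of 35 genes of G2/M and mitosis, 34 had a negative log2 fold change with a median of -0.15 (camera adjusted p = 1.79e-13; adjusted p = 0.124 with an estimated correlation). No single member fell over all genes, and 7 fell when adjusted over the list alone. Among them were CDC20, an activator of the anaphase-promoting complex (-0.30, SE 0.063), FOXM1, a transcription factor of mitotic genes (-0.28, SE 0.061), the proliferation marker MKI67 (-0.37, SE 0.10) and UBE2C (-0.25, SE 0.070). The list median was -0.20 within the low-share and -0.20 within the high-share libraries. Genes of DNA damage repair had a median of -0.08, and 20 of 21 were negative (camera adjusted p = 2.29e-05; adjusted p = 0.124 with an estimated correlation). None fell over all genes, and 6 fell over the list alone, among them the exonuclease gene EXO1 (-0.30, SE 0.069) and the recombination gene RAD54L (-0.45, SE 0.14). The 16 genes of PCNA ubiquitination and translesion synthesis did not shift as a list (camera adjusted p = 0.664, median 0.01). SHPRH was its one member that rose over all genes. RAD18, the ligase that adds the first ubiquitin to PCNA, had a log2 fold change of -0.26 (SE 0.077, edgeR adjusted p = 0.204) and fell when adjusted over the list alone.

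**Figure D2:**
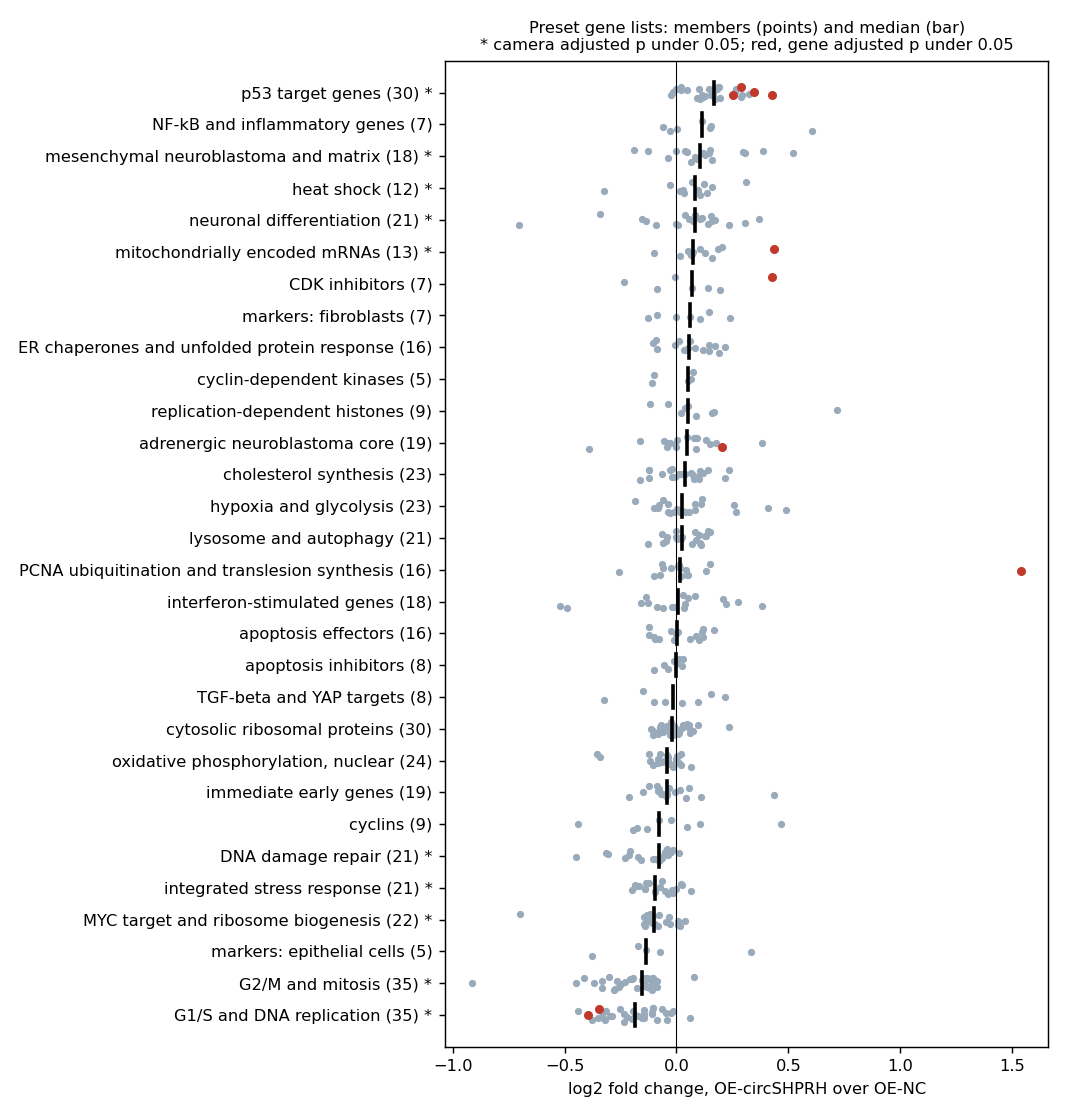
Log2 fold change of OE-circSHPRH over OE-NC (x axis) for the tested members (points) of the 30 gene lists (y axis, number of tested members in brackets), with the list median as a bar, red points for genes at an edgeR adjusted p under 0.05 and a star for a camera adjusted p under 0.05. The p53 targets have the highest median, 0.17, and the G1/S genes the lowest, -0.19.

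**Figure D3:**
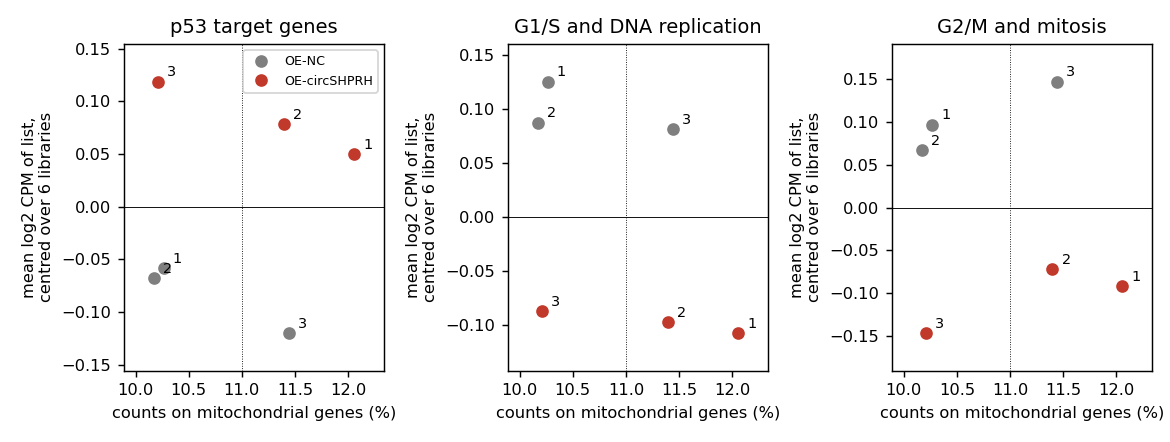
Mean log2 CPM of each of 3 lists per library, centred over the 6 libraries (y axis), against the percent of counts on mitochondrial genes (x axis), with the replicate number beside each point and a dotted line at 11%. The 3 OE-circSHPRH libraries lie above 0 for the p53 targets and below 0 for the G1/S and G2/M lists, on both sides of the line.

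The lists of growth and of the integrated stress response also shifted downward. For MYC targets and ribosome biogenesis, 17 of 22 log2 fold changes were negative with a median of -0.10 (camera adjusted p = 0.000163; adjusted p = 0.124 with an estimated correlation). None passed over all genes, and 3 fell over the list alone: MYBBP1A (-0.14), CAD, an enzyme of pyrimidine synthesis (-0.15), and NOP2 (-0.70, SE 0.22). For the integrated stress response, the ATF4-driven programme of amino acid supply, 18 of 21 were negative with a median of -0.10 (camera adjusted p = 0.000212). The list did not pass with an estimated correlation (adjusted p = 0.298) or by fry (adjusted p = 0.0537). Again none passed over all genes, and 9 fell over the list alone, among them the serine synthesis gene PHGDH (-0.18, SE 0.043) and TRIB3 (-0.14, SE 0.041). This list was also lower in the high-share than in the low-share libraries (camera adjusted p = 0.0252). That test used only the preset correlation, against 0.17 estimated between the groups. It had no group term, although most high-share libraries were OE-circSHPRH. The list median was -0.07 within the low-share and -0.06 within the high-share libraries. The cytosolic ribosomal proteins did not pass between the groups (median -0.02, camera adjusted p = 0.664), and RPS23 was the one member that rose over the list alone (0.24, SE 0.055).

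Lists of differentiation and matrix genes shifted upward. For mesenchymal neuroblastoma and matrix genes, 14 of 18 log2 fold changes were positive with a median of 0.10 (camera adjusted p = 0.00428; adjusted p = 0.124 with an estimated correlation). None rose over all genes, and NOTCH3 was the one that rose over the list alone (0.15, SE 0.042). For neuronal differentiation, 15 of 21 were positive with a median of 0.08 (camera adjusted p = 0.0249; adjusted p = 0.323 with an estimated correlation). None rose over all genes, and 5 rose over the list alone, among them DCX, a microtubule protein of young neurons (0.31, SE 0.078), and SCG2, which encodes a granin of secretory granules (0.16, SE 0.045). The neuronal list no longer passed with the library class, low or high mitochondrial share, as a term (adjusted p = 0.134), nor without OE-NC replicate 1 (0.0608), OE-NC replicate 2 (0.160), OE-circSHPRH replicate 1 (0.248) or OE-circSHPRH replicate 2 (0.0716). The adrenergic neuroblastoma genes did not pass as a list (median 0.05, camera adjusted p = 0.113), except with the GC and length trend removed (adjusted p = 0.0475), but RET, which encodes a receptor tyrosine kinase of sympathetic neurons, rose (0.20, SE 0.040, edgeR adjusted p = 0.0409). RET passed in 2 of the 6 fits with a library left out (highest edgeR adjusted p = 0.342). Over the adrenergic list alone 3 genes rose and 1 fell, the last being CHGA, which encodes the granule protein chromogranin A (-0.16, SE 0.046). For heat shock genes 10 of 12 were positive with a median of 0.08 (camera adjusted p = 0.0462; adjusted p = 0.271 with an estimated correlation). None rose over all genes and 2 rose over the list alone, HSPA1A (0.31) and HSP90AA1 (0.14). With the library class as a term the adjusted p of the heat shock list was 0.0555, and it was 0.0700 to 0.168 with any library but OE-NC replicate 2 left out.

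Of the 13 mitochondrially encoded mRNAs, 12 had a positive log2 fold change with a median of 0.07 (camera adjusted p = 0.0249; adjusted p = 0.576 with an estimated correlation). MT-ATP8 rose from 126 ± 3.58 to 170 ± 4.08 CPM (SD, n = 3 each; log2 fold change 0.43, edgeR adjusted p = 5.12e-05), and 4 members rose over the list alone. MT-CO2 had a log2 fold change of 0.19 (SE 0.065) and MT-ND6 of 0.20 (SE 0.055). These mRNAs were also higher in the high-share libraries (camera adjusted p = 1.16e-08), which their own counts define. Within the low-share libraries the median was -0.0080 and within the high-share libraries 0.02, and with the library class as a term the list no longer passed (adjusted p = 0.327), nor did it without OE-NC replicate 1 (0.192), OE-NC replicate 2 (0.187), OE-circSHPRH replicate 1 (0.305) or OE-circSHPRH replicate 2 (0.0957). Nuclear genes of oxidative phosphorylation did not pass between the groups (median -0.04, camera adjusted p = 0.066). They did without OE-NC replicate 3 (adjusted p = 0.0366) or OE-circSHPRH replicate 3 (adjusted p = 0.0025). These fits left only low-share libraries in OE-NC or only high-share libraries in OE-circSHPRH, so group partly coincided with library class. With the library class as a term the camera adjusted p was 0.287. The median was -0.0060 within the low-share and -0.05 within the high-share libraries. Nuclear genes of oxidative phosphorylation were lower in the high-share libraries (camera adjusted p = 0.000534), as were the cytosolic ribosomal proteins (camera adjusted p = 0.0252). These tests of the high-share libraries used only the preset correlation of 0.01. Between the groups 0.25 and 0.30 were estimated for these lists, in that order.

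Among the other protein-coding genes that rose, the largest log2 fold changes were those of the interferon-inducible gene TRIM22 (0.52, SE 0.10), the cadherin gene CDH11 (0.40, SE 0.059), C8orf59 (0.34, SE 0.067), the phosphatase gene PTPN12 (0.31, SE 0.057) and the MAP kinase phosphatase gene DUSP4 (0.30, SE 0.044). TRIM22 lies on chromosome 11 (5689689 to 5737089) and CDH11 on chromosome 16 (64943753 to 65126112). Among those that fell, GPR89A (chromosome 1, 145607990 to 145670648) had a log2 fold change of -0.80 (SE 0.16), but it has near-identical copies that can share its reads, and its value is uncertain. The others were the polycomb-associated gene PHF19 (-0.38, SE 0.078), the kinesin gene KIF22 (-0.38, SE 0.064), MYBL2, a transcription factor of the cell cycle (-0.28, SE 0.050), and SEC14L1 (-0.23, SE 0.046). The edgeR adjusted p of these 10 genes ran from 0.00474 for CDH11 to 0.0493 for GPR89A and PHF19. With each library left out in turn, none of the 10 passed in all 6 fits: CDH11 and DUSP4 passed in 4, KIF22 in 3, C8orf59, PTPN12 and MYBL2 in 2, and TRIM22, GPR89A, PHF19 and SEC14L1 in 1. The highest adjusted p in these fits was 0.294 for TRIM22, 0.342 for GPR89A and 0.317 for PHF19. The authors' adjusted p is 1 for these 3 genes, as it is for 21740 genes. That value can mark genes left out of the authors' adjustment, so it does not count against them. Their unadjusted p by the authors' test was 0.000142, 0.00819 and 0.000334. Further genes past the threshold, outside the naming rule and chosen after their values were seen, were WSB1 (0.28), NQO1 (0.28), TFPI2 (0.26), RGS5 (0.25), IDS (0.23) and DLK1 (0.23). Of those not coding for protein, also outside the rule, ZFAS1 (-0.39) and SNHG6 (-0.33), which host small nucleolar RNAs, fell. With each library left out, ZFAS1 passed in all 6 fits, WSB1 in 3, SNHG6, TFPI2, RGS5, IDS and DLK1 in 2, and NQO1 in 1. ZFAS1 and ROR1-AS1 (0.47) are annotated as antisense, and because use of strand in the counting is not given, reads of a gene on the other strand may be included. The pseudogenes MTATP6P1 (0.54), BX679664.3 (0.47) and SMG1P2 (-0.99) share sequence with other loci and are uncertain too. MTATP6P1 was also higher in the high-share than in the low-share libraries (0.51, SE 0.10, edgeR adjusted p = 0.0150). Its difference between the groups was 0.38 within the low-share and 0.43 within the high-share libraries.

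The remaining lists did not pass camera in the main setting. Their adjusted p was 0.0749 for ER chaperones and the unfolded protein response (median 0.06), 0.0749 for lysosome and autophagy genes (median 0.03), 0.0833 for replication-dependent histones (median 0.05) and 0.242 for cholesterol synthesis (median 0.04). The ER list passed with the GC and length trend removed (adjusted p = 0.0425), the lysosome and autophagy list with the mitochondrial percent as a covariate (adjusted p = 0.0471), and the histones by fry (adjusted p = 0.0289). HSPA5, the main chaperone of the ER, rose over its list alone (0.17, SE 0.044). NF-kB and inflammatory genes had a median of 0.12 over 7 tested genes (adjusted p = 0.316), hypoxia and glycolysis genes of 0.03 (adjusted p = 0.535) and immediate early genes of -0.04 (adjusted p = 0.472). For the 18 interferon-stimulated genes the median was 0.0084 and the mean -0.02, with camera pointing downward (adjusted p = 0.701). For TGF-beta and YAP targets the median was -0.01 while camera pointed upward (adjusted p = 0.883). Among markers of other cell types, 5 epithelial genes (median -0.14, adjusted p = 0.749) and 7 fibroblast genes (median 0.06, adjusted p = 0.52) did not pass as lists, and of these LUM rose over its list alone (0.24, SE 0.062). Too few markers of blood cells (2), Schwann and glial cells (4) and endothelial cells (0) were tested for a list test.

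By the authors' deposited table, 73 genes had an adjusted p under 0.05, 46 higher and 27 lower in OE-circSHPRH, and 25 of the 31 genes called here were among them, each in the same direction. It gives SHPRH a log2 fold change of 1.54 and CDKN1A of 0.43. With each library left out in turn, SHPRH, CDKN1A, MT-ATP8, TP53INP1 and ZFAS1 passed in all 6 fits, while MCM2 passed in 4, MCM5 in 3, ZMAT3 in 2 and SESN1 in 1 (highest edgeR adjusted p = 0.154, 0.0657, 0.103 and 0.235). Over these fits the log2 fold change ran from -0.32 to -0.37 for MCM2, -0.37 to -0.42 for MCM5, 0.24 to 0.27 for ZMAT3 and 0.26 to 0.31 for SESN1. Of the 31 called genes, 5 passed in all 6 fits. The number of genes called moved with the libraries used, as 4 rose and 1 fell without OE-circSHPRH replicate 2, and 142 rose and 169 fell without OE-circSHPRH replicate 3. The latter fit kept only high-share libraries in OE-circSHPRH, so group and mitochondrial share partly coincided in it. The number called also moved with the model: 49 rose and 28 fell with DESeq2, and 104 rose and 67 fell with the library class as a term in edgeR.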

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

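The direction and the call of SHPRH and CDKN1A held under every alternative run, with log2 fold changes of 1.44 to 1.62 and 0.40 to 0.45. The robust fit, the fit without mitochondrial genes, the GC and length correction, the mitochondrial covariate, the p53 list without CDKN1A and the library class term were chosen after seeing the data. Of the counts of genes, which were 21 higher and 10 lower, those that moved by over 1.5 times were as follows. DESeq2 gave 49 higher and 28 lower, with 25 of the 31 genes among them. No low-count filter gave 116 and 78, the robust fit 36 and 24, and the library class term 104 and 67, with 31, 29 and 31 of them. With the replicate number as a block, 4 were higher and 2 lower. No pairing by number was seen: deviations of same-numbered libraries correlated at -0.0445, -0.0266 and -0.106, and no library correlated best with its own number. This cannot exclude a pairing, since same-numbered libraries fall on opposite sides of the mitochondrial share. Leaving out single libraries gave 4 to 142 higher and 1 to 169 lower: 4 and 2 without OE-NC replicate 1, 7 and 4 without OE-NC replicate 2, 13 and 6 without OE-NC replicate 3, 4 and 1 without OE-circSHPRH replicate 2, and 142 and 169 without OE-circSHPRH replicate 3. At 2-fold or more, 1 gene was higher and 0 lower. That became 7 and 3 without a filter, 2 and 4 with the library class term, 1 lower with the block, and 1 to 6 higher and 0 to 11 lower with single libraries left out. Of the 31 called genes, 5 passed in all 6 fits with a library left out. The common dispersion was 0.00199 without OE-circSHPRH replicate 3 and 0.0017 with the library class term, against 0.00287 in the main fit. It was 0.00345 without OE-NC replicate 1 and 0.00374 with the block. Without a filter the prior degrees of freedom were infinite, against 14.9, so gene variances were drawn fully to the trend. The spread was also lower without OE-circSHPRH replicate 1 (0.002245), a fit whose counts did not move by over 1.5 times. Without OE-circSHPRH replicate 3, only high-share libraries were left in OE-circSHPRH, while OE-NC replicates 1 and 2 were low-share. Library class thus partly coincided with group there, and the 142 and 169 genes can include differences between the classes. The estimated spread went with several of these moves, but their causes were not told apart.

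Of the 10 gene lists past the threshold, 1 held with an estimated correlation, and the other settings gave 7 to 12. The p53, G1/S and G2/M lists kept their direction and call with each library left out (highest adjusted p = 3.33e-07), and the p53 list without CDKN1A had an adjusted p = 2.76e-10. With the library class term the neuronal, heat shock and mitochondrial mRNA lists no longer passed (adjusted p = 0.134, 0.0555 and 0.327). The neuronal list also lost its call by fry (0.069), without a filter (0.0765), with the block (0.0740) and with the mitochondrial covariate (0.160). The heat shock list lost it without a filter (0.0896), with the block (0.105) and without mitochondrial genes (0.0502). The mitochondrial mRNA list lost it by fry (0.319), with the block (0.0740) and with the covariate (0.739). No called result reversed. In simulated counts edgeR called 49.3% of the smallest changes; depth was not varied, so what it limits was not tested.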

Other observations

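The tests of MT-ATP8 and MTATP6P1, those of the added lists over the library class, the test of mitochondrial reads in the split of the libraries, and the library class term were chosen after the results they bear on were seen.

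Further sets of genes were tested beside those already described. After the first p53 list was seen to shift upward, a second set of p53 target genes, none of them in the first list, was tested in the same 6 libraries. It had 18 positive log2 fold changes among 18 tested, with a median of 0.10. DRAM1, a lysosomal regulator of autophagy (0.28, SE 0.075), and ASCC3 (0.17, SE 0.046), both chosen after their values were seen, rose when adjusted over the list alone, and none did over all genes. The set shifted upward by camera (p = 6.04e-07; p = 0.00570 with an estimated correlation), so a change of p53 targets as a class remains a candidate explanation for the first list. After ZFAS1 and SNHG6 were seen to fall, 16 other genes listed as long noncoding hosts of small nucleolar RNAs were tested, and 14 had a negative log2 fold change with a median of -0.11. C6orf48 is among the 16, though the deposited annotation marks it as protein-coding. Camera gave p = 0.00334 for this set, but p = 0.282 with an estimated correlation, and SNHG15 (-0.19, SE 0.053), EPB41L4A-AS1 (-0.22, SE 0.064) and SNHG1 (-0.15, SE 0.046), chosen likewise, fell when adjusted over the list alone, while none did over all genes. The set also went with the mitochondrial share: 13 of the 16 had a negative log2 fold change of the high-share over the low-share libraries, with a median of -0.14 (camera p = 8.42e-05; p = 0.0934 with an estimated correlation), and 3 of them passed, C6orf48 (-0.38), SNHG8 (-0.29) and LRRC75A-AS1 (-0.17). With the library class as a term the set still shifted downward in OE-circSHPRH (camera adjusted p = 0.0361 over both added sets) but by a median of -0.07, and the median difference was -0.04 within the low-share and -0.11 within the high-share libraries. A shared fall of these host genes with OE-circSHPRH is thus a hypothesis that rests on the preset correlation, and part of it stays open as a difference between the kinds of library.

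The p53 list shifted upward and the G1/S and G2/M lists downward by camera, though only 4 of 30, 2 of 35 and 0 of 35 members passed over all genes, and with an estimated correlation the p53 and G2/M lists did not pass (adjusted p = 0.124 for both). A bias by gene length or GC content is argued against as the whole cause, since the smallest absolute median of the 3 lists was 0.16 after both trends were removed from each library, and all 3 lists still passed camera with the preset correlation. A difference in the mitochondrial share is argued against as well, since the smallest absolute median was 0.18 with that share as a covariate. The effect of the transfected construct, the candidate explanation given by the design, stays open as a hypothesis, as does any difference between the cultures that the labels do not record.

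MT-ATP8 and the pseudogene MTATP6P1 were both higher in OE-circSHPRH, and for MT-ATP8 a higher share of mitochondrial RNA overall is argued against, since the median log2 fold change of the other 12 mitochondrially encoded mRNAs was 0.0697 against 0.43 (SE 0.045) for MT-ATP8, whose difference was 0.49 within the low-share and 0.38 within the high-share libraries. MTATP6P1 also went with that share: it was 0.51 (log2, SE 0.10) higher in the high-share libraries, and OE-circSHPRH replicate 3 (354 CPM) lay close to OE-NC replicate 3 (345 CPM). The share is argued against only as its whole cause, since its log2 fold change of 0.54 was 0.41 with the library class as a term and 0.36 with the mitochondrial percent as a covariate, at least 7.21 standard errors above 0. Over its alternative settings, however, the adjusted p ran from 1.10e-31 (no low-count filter) to 0.490 (robust fit). MTATP6P1 passed in 2 of the 6 fits with a library left out (highest edgeR adjusted p = 0.317). By the authors' test its adjusted p was 0.259, so its call is uncertain. MTATP6P1 is a nuclear copy of MT-ATP6, and reads moved to it from MT-ATP6 stay open: its gain of 134 CPM would need a log2 fall of -0.0386 in MT-ATP6 (5055 CPM in OE-NC), too small to tell from no fall by the log2 fold change of MT-ATP6 (0.07, SE 0.060) or by its ratio to the other mitochondrial mRNAs (-0.02, SE 0.019). Also open, and not tested, is how reads were assigned where MT-ATP8 overlaps MT-ATP6.

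The libraries also divided in a way that the groups do not give. The split of OE-NC replicates 1 and 2 and OE-circSHPRH replicate 3 from the other 3 libraries gave 107 genes, 81 of them lower and 26 higher in the libraries with the higher mitochondrial share, and 1 of the 107, MTATP6P1, was among the 31 genes called between the groups. Among them, chosen after their values were seen, were EIF3C (-1.40), RPL26 (-0.92), COX6A1 (-0.67) and MT-CO1 (0.25), as log2 fold changes of the high-share over the low-share libraries. The largest was that of MAGED4 (3.31, edgeR adjusted p = 3.56e-07). Whether reads shared with similar genes contribute to any of these values was not tested. Gene length and GC content are argued against as the whole cause, since limma called 110 genes before and 68 after both trends were removed. Part of the split did go with them, and gene length correlated with its log2 fold changes (Spearman 0.26 over 10904 genes). Mitochondrial genes were 14 of the 107, so the split reached beyond them. Without mitochondrial genes 97 were called, but leaving out so few could hardly have lowered the count much. That test therefore decides nothing on mitochondrial reads as a source. A difference in library preparation or RNA quality stays open as a candidate source of the rest, and no biological explanation was tested.

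The 6 libraries can be split in 10 ways into groups of 3, too few for a share under 0.05. The real split gave 31 genes and the highest of the others 107, so that 2 of the 10 splits gave as many. At 2-fold or more the real split gave 1 gene and the highest other 4, and 4 of the 10 splits gave as many. For gene lists the real split gave 10 and the highest other 5, and 1 of the 10 splits, the real one, gave as many. The split with 107 genes and 5 lists, several times the real count of genes, is the one that follows the mitochondrial share, and it points to a structure of the samples. With the library class as a term, 104 genes were higher and 67 lower in OE-circSHPRH.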
